A study of Mus musculus with 37 samples.

How the data were processed

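The files analysed here hold T cell receptor beta (TRB) repertoires from lymph nodes of 37 mice, 1 library per mouse. Genomic DNA was amplified over the rearranged TRB locus and sequenced, so every read stands for a rearranged gene and not for a transcript. A clonotype is a rearranged sequence with its variable segment (TRBV), its joining segment (TRBJ) and the third complementarity-determining region (CDR3), the stretch of the receptor that contacts the peptide.

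Per the file headers, each deposited table gives for every clonotype its segments, its CDR3 as nucleotides and as amino acids, its clone count and 2 rescaled counts. The deposited clone count is in counts, whole reads per clonotype with no normalization. The deposited "normalized clone count" and "nb clone count" are scores, made by the authors from the clone count and rounded to whole numbers. The ratio of score to count was constant within a TRBV and TRBJ pair and the same in every library, which was checked on the files. For the normalized clone count this factor ran from 0.172 to 75.5 over 167 pairs, and in the 147 pairs with enough reads in at least 2 libraries the median spread between libraries was 0.614%, with a maximum of 4.60%. For the nb clone count it ran from 0.292 to 17.4. The factors rescale 1 segment pair against another and leave depth unscaled, and how they were derived, the aligner, the clonotype caller and the genome build are not given in the sources used here. All 37 files listed productive CDR3 sequences alone, with 0 unproductive and 0 duplicated entries, so the planned repeat with all listed clonotypes was not run.

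Samples were grouped by the genotype, treatment and time labels into 9 groups at 2 time points. The labels do not spell out the suffixes R and NR or the name WTNT, and these are used as written. Replicate numbers follow the order of deposition and do not pair mice. The 8 comparisons, their tests, the fixed segment lists and the rule for named items were set before the data were examined.

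Libraries held 90648 to 2831566 reads, with a median of 1455363. Reads come from PCR without molecular identifiers and are not independent molecules, so each interval and each limit set by a count of 0 covers counting error only. Shares of reads in 1 library are given with 95% Wilson intervals, and a limit for a clonotype with no read was set at 3 reads per library, scaled by the factor of its segment pair and averaged over the libraries of the group. Normalised shares are rescaled values and carry no binomial interval.

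From the normalized clone counts the following were computed for each library. Clonality was 1 minus the Shannon entropy over the logarithm of the number of clonotypes. Richness was the number of clonotypes after thinning to 222369 reads without replacement. The library d95 PLX+PTX+aPD-1_NR replicate 1, with 90648 reads, fell under 10% of the median total and received no richness value. Also computed were the percent of normalised counts in the 10 most abundant clonotypes, the percent in expanded clonotypes that each held at least 0.1% of the library, and the mean CDR3 length weighted by normalised count. Group means of these measures were compared by exact permutation tests, 2-sided, or by permutation tests with 100000 resamples where exact enumeration was too large. Between days, labels were permuted within each treatment group. Benjamini-Hochberg adjustment covered the 32 tests of 4 measures in 8 comparisons, and the 8 tests of CDR3 length separately. The threshold was an adjusted p of 0.05.

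Segment usage was tested with limma 3.58.1 in R 4.3.3 on log2 of the percent of normalised counts plus 0.01, for segments with a mean share of at least 0.1%, which left 24 segments. The d105 libraries shared 1 fit, the d95 libraries another, and a separate fit held the 32 MMTV-PyMT libraries of both days. Because reads of a segment are not independent molecules and shares form a composition, log shares were the main test, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on reads per segment were alternatives. Clonotypes with the same segments and the same amino acid CDR3 were merged for sharing. Merged clonotypes found in at least 50% of the libraries of a fit were tested with limma on log2 of normalised counts per 1000000 (CPM) plus 10, which gave 5242 clonotypes at d105, 964 at d95 and 2394 over both days. Adjustment was per comparison. Changes of an effect between days were tested for segments as limma interaction contrasts, and for the scalar measures by permuting days within treatments. The same contrasts for shared clonotypes were chosen after seeing the data. Overlap between mice was the Morisita-Horn index of merged clonotypes, and the mean index within groups minus that between groups was tested by permutation of mice.

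Segments were named when they passed the threshold, up to 10 per direction, or when they stood on a fixed list. The lists were the segments removed by the deletion known in FVB/N mice (TRBV12-1, TRBV12-2, TRBV13-1, TRBV13-2, TRBV13-3, TRBV14, TRBV15, TRBV16 and TRBV17), segments engaged by superantigens of mouse mammary tumor virus (TRBV31, TRBV26, TRBV19 and TRBV29), segments favoured by invariant NKT and MAIT cells (TRBV1, TRBV29, TRBV19 and the TRBV13 family), and the TRBJ1 and TRBJ2 clusters. TRBV29 and TRBV19 stand on both of the last V lists. Clonotypes were named when they were among the 5 with the lowest p in a direction past the threshold, among the 5 found in the most libraries, or the most abundant of a group. Segments and clonotypes outside this rule were chosen after their values were seen and are marked as such.

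The limma step was tested on simulated data made from these libraries, and the permutation step on random draws from a normal distribution. With a simulated log2 difference of 0.5 in segments, limma recovered 90.4% of the changed segments for R against NR at d105 and 75.6% for R against NR at d95, of 24 segments each. With a simulated log2 difference of 2 in shared clonotypes, it recovered 50% of the changed ones among 5242 for R against NR at d105, 1% among 964 for R against NR at d95, 0% among 964 for PLX+PTX against PTX at d95 and 90% among 2394 between days. The permutation test of 6 against 4 samples gave p under the threshold in 5.5% of simulations without a difference and in 75.3% with a shift of 2 SD. No values of these libraries entered it, so the 75.3% need not hold for measures with a skewed spread.

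Alternatives fixed in advance were the raw clone counts, merged amino acid clonotypes, clonotypes of 1 read left out, thinned libraries, a thinning depth of 111184 reads, the low library left out, each library left out in turn, the block of mouse numbers as covariate or stratum at d105, each clonotype counted once, other pseudocounts (0.1% for segments, 1 and 50 CPM for clonotypes), no filter on the share, detection in 80% of libraries, a fit of only the compared groups, edgeR, DESeq2, and a Jaccard overlap. The nb clone counts, the repeats without the FVB/N deletion segments, raw counts for shared clonotypes and overlap, and other settings for the changes between days were chosen after seeing the data. The block of mouse numbers entered only the d105 comparisons of R against NR and of aPD-1 added to PLX+PTX. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.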

Results

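T cell receptor beta repertoires were read from lymph node DNA of 37 mice. Of these, 32 carried the MMTV-PyMT transgene, which drives mammary tumors, and 5 were FVBN mice of the group named WTNT, whose name the labels do not spell out. The treatments were PLX3397 (pexidartinib), an inhibitor of the receptor CSF1R on macrophages, PTX, the chemotherapy of the series title, and an antibody against PD-1 (aPD-1), the inhibitory receptor on T cells. PLX3397 was given at 40 mg/kg/day from an age of 80 days, PTX at 10 mg/kg every 5 days from an age of 85 days, and aPD-1 as 1.0 mg and then 0.5 mg every 5 days from 87 days. At d105 there were 6 mice with all 3 agents and the suffix R, 4 with the suffix NR, 6 with PLX3397 and PTX (PLX+PTX), 2 with PTX alone and the 5 WTNT mice. At d95 there were 5 R, 3 NR, 3 PLX+PTX and 3 PTX mice. The labels do not say what R and NR stand for.

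Libraries at d105 held 1090573 to 2831566 reads, with a median of 1669178, and 23679 to 91867 clonotypes. Libraries at d95 held 90648 to 917752 reads, with a median of 453920, and 2470 to 32057 clonotypes. The ranges of reads at the 2 days did not overlap, so day and sequencing yield cannot be separated. Values within a group are means with SD, and every test was 2-sided.

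Most receptors were private to a mouse. Of 1002058 amino acid clonotypes, 803728 (80.2%) were found in 1 library only, and 2554 were found in at least 50% of libraries, where they held 9.20% ± 1.22 (SD, n = 37) of normalised counts. The 3 clonotypes found in all 37 libraries were TRBV3 TRBJ2-7 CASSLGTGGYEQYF with 0.0199% ± 0.0138, TRBV3 TRBJ2-7 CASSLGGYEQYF with 0.0179% ± 0.0146 and TRBV19 TRBJ2-7 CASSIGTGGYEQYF with 0.0157% ± 0.0144 of normalised counts. TRBV4 TRBJ2-7 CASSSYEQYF, with 0.137% ± 0.0660, and TRBV5 TRBJ2-7 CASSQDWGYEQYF, with 0.0268% ± 0.0192, were found in 36.

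No clonotype dominated a library. The highest share of a d105 library was 0.556% of normalised counts, for TRBV26 TRBJ2-3 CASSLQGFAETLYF in PLX+PTX replicate 3. It rested on 302 reads, 0.0167% of the reads of that library (95% Wilson interval 0.0149 to 0.0187), since the authors' factor for this segment pair is the highest. The top clonotypes of the other d105 groups were TRBV5 TRBJ2-5 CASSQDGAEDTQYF in NR replicate 1 (0.256% of normalised counts), TRBV4 TRBJ2-7 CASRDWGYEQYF in R replicate 1 (0.228%) and TRBV13-2 TRBJ2-5 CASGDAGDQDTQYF in PTX replicate 2 (0.186%) and WTNT replicate 4 (0.205%). At d95, TRBV4 TRBJ2-7 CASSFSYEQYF led in PLX+PTX replicate 2 (0.406%), PTX replicate 1 (0.293%) and R replicate 3 (0.278%), and TRBV4 TRBJ2-7 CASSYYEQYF led in NR replicate 1 (0.599%). Ranked by reads, an order chosen after the values were seen, 7 of the 9 groups had another leader. The highest shares of reads were those of TRBV13-2 TRBJ2-5 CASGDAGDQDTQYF, with 0.649% (95% Wilson interval 0.637 to 0.662) in WTNT replicate 4, 0.549% (0.535 to 0.563) in PTX replicate 2 and 0.499% (0.490 to 0.508) in d105 R replicate 3, where it was a new leader. Other new leaders were TRBV26 TRBJ1-2 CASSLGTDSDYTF in d105 NR replicate 1, with 0.232% of reads (95% Wilson interval 0.225 to 0.239), and TRBV1 TRBJ1-2 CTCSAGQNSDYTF in d95 PLX+PTX replicate 2, with 0.127% (0.115 to 0.139). TRBV1 TRBJ1-1 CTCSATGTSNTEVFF led in d95 R replicate 5 (0.266%, 0.252 to 0.280) and TRBV19 TRBJ2-7 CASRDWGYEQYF in d95 NR replicate 1 (0.263%, 0.231 to 0.298). TRBV26 TRBJ1-1 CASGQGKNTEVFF led in d105 PLX+PTX replicate 4 (0.262%, 0.255 to 0.269) and TRBV19 TRBJ2-7 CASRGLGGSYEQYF in d95 PTX replicate 2 (0.0990%, 0.0908 to 0.108).

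FVB/N mice are known to lack a stretch of the TRBV locus. No segment of that deletion list reached the share of normalised counts needed for testing, so limma, edgeR and DESeq2 tested 0 of its 9 segments at that share. TRBV13-2 reached it at d105 in raw reads and nb clone counts and was not called by limma, with log2 differences of -3.25 and -3.26 for PLX3397 added to PTX (adjusted p 0.0735 and 0.0886, and 0.127 without a filter). Without a filter on the share, which was run in limma only, TRBV12-2 was called for PLX3397 added to PTX at d105 (log2 -0.39, adjusted p 0.00719, in the 1 alternative that tested it). TRBV13-2 (1.47), TRBV13-3 (0.54), TRBV14 (0.24) and TRBV16 (0.16) were called between days, and 0 in the other 6 comparisons, with at most 1 at an unadjusted p under 0.05. Their reads made up 0.448% ± 0.325 of reads in PTX mice (n = 2) and 0.275% ± 0.337 in WTNT mice (n = 5) at d105. The means of the other d105 groups were 0.195% in NR, 0.158% in R and 0.0501% in PLX+PTX, and those at d95 were 0.0611% in NR, 0.0276% in PTX, 0.0149% in PLX+PTX and 0.00901% in R. The highest share was 0.838% in WTNT replicate 4, or 12367 of 1475178 reads (95% Wilson interval 0.824 to 0.853). TRBV13-2 TRBJ2-5 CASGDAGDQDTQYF alone held 71.3% of the list's reads at d105. No TRBV31 clonotype was listed in any of the 37 libraries.

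The R and NR mice at d105 received the same 3 agents, and the comparison asks whether their repertoires differed. TRBV19, a superantigen segment, held 3.58% ± 0.75 of normalised counts in R (n = 6) and 4.48% ± 0.63 in NR (n = 4), a log2 difference of -0.34 ± 0.14 (SE). It did not pass the threshold in limma (adjusted p 0.178). TRBV5, with a log2 difference of 0.14, TRBJ2-1, with 0.06, TRBJ2-5, with 0.14, TRBV30, with 0.31, and TRBV3, with -0.12, also had an unadjusted p under 0.05 and the same adjusted p, and were chosen after their values were seen. TRBV1 (0.03), TRBV26 (0.09) and TRBV29 (0.07) lay near 0 on the log2 scale. In limma 0 of 24 segments passed the threshold and 6 had an unadjusted p under 0.05, against 0 and 4 in both edgeR and DESeq2. Adjusted over the list alone, 0 segments passed in the superantigen, invariant T cell, TRBJ1 and TRBJ2 lists, as over all tested. Without NR replicate 1, 7 segments passed, among them TRBV19 at -0.44 (adjusted p 0.0367), TRBV26 at 0.21 and TRBV5 at 0.16, and without R replicate 6, TRBV19 at -0.43 and TRBV5 at 0.16 passed. Over 10 alternatives that kept all libraries, the adjusted p of TRBV19 ran from 0.0688 to 0.379. Of 5242 shared clonotypes, limma called 0, with 289 at an unadjusted p under 0.05. Clonality was 0.0579 ± 0.0036 in R and 0.0556 ± 0.0063 in NR (exact permutation p 0.476, adjusted 0.693), and richness was 43887 ± 10020 against 44550 ± 7833 (exact permutation p 0.914). Overlap within the groups was no higher than between them (exact permutation p 0.524).

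Adding aPD-1 to PLX+PTX was examined at d105 in 10 mice with all 3 agents against 6 with PLX+PTX. TRBV1 (0.02), TRBV19 (0.13), TRBV26 (-0.08) and TRBV29 (-0.02) differed little on the log2 scale. Limma, edgeR and DESeq2 each called 0 of 24 segments, and 0 had an unadjusted p under 0.05 in each. Adjusted over the list alone, 0 segments of every tested list passed, as over all tested. Among 5242 shared clonotypes limma called 0, with 259 at an unadjusted p under 0.05. Expanded clonotypes held 0.224% ± 0.172 of normalised counts with aPD-1 and 0.440% ± 0.166 without (exact permutation p 0.0287, adjusted 0.131), a difference that had the other sign in raw reads, at 0.0546 percentage points. The 10 most abundant clonotypes held 0.791% ± 0.166 against 0.963% ± 0.160 (exact permutation p 0.0624, adjusted 0.182). Overlap did not differ (exact permutation p 0.605).

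Adding PLX3397 to PTX was examined at d105 in 6 PLX+PTX mice against 2 PTX mice. Both PTX mice came from the block of higher mouse numbers, whereas PLX+PTX replicates 1, 2, 5 and 6 came from the lower. The block did not enter these tests, so it was not told apart from PLX3397. TRBV26 held 12.3% ± 0.87 of normalised counts with PLX3397 and 10.2% ± 1.34 without, a log2 difference of 0.28 ± 0.10 (limma adjusted p 0.339). Adjusted over the list alone, TRBV26 was the 1 superantigen segment that passed (adjusted p 0.0424), against 0 over all tested, and 0 passed in the invariant T cell, TRBJ1 and TRBJ2 lists either way. Limma called 0 of 24 segments and had 2 at an unadjusted p under 0.05, TRBV26 and TRBJ1-6, while edgeR called 2 with 5 and DESeq2 2 with 3. The segments called by edgeR were TRBV26 at 0.27 and TRBJ1-6 at 0.23 (adjusted p 0.0143 each), and over 9 alternatives the adjusted p ran from 0.0143 to 0.467 for TRBV26 and from 0.0143 to 0.528 for TRBJ1-6. TRBV1 (0.02), TRBV19 (-0.13) and TRBV29 (-0.04) stayed near 0. No shared clonotype of 5242 was called by limma (0), with 520 at an unadjusted p under 0.05. TRBV26 TRBJ2-7 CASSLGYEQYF, chosen after its values were seen, was found in 6 of 6 PLX+PTX mice at a mean of 209 normalised CPM (34.3 to 315) and in 0 of 2 PTX mice (limma adjusted p 0.296). The PLX+PTX mean was 74.2-fold the PTX floor of 3 reads per library, which covers the counting of reads only and gives no lower bound. Richness was 45932 ± 8997 against 24696 ± 9093, at the smallest p that 28 regroupings can give (exact permutation p 0.0357, adjusted 0.139). Overlap gave an exact permutation p of 0.0714 (adjusted 0.233).

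Mice with and without the MMTV-PyMT transgene were compared at d105, as 18 MMTV-PyMT mice against the 5 WTNT mice, for which the labels list none of the 3 agents. TRBV1 (0.02), TRBV19 (-0.06), TRBV26 (0.01) and TRBV29 (0.06) had log2 differences near 0. Limma called 0 of 24 segments with 0 at an unadjusted p under 0.05, edgeR 0 with 3 and DESeq2 0 with 0. Adjusted over the list alone, 0 segments of every tested list passed, as over all tested. When each clonotype was counted once, TRBV20 at -0.20 and TRBV29 at 0.08 passed (adjusted p 0.034 each), and the adjusted p of both ran up to 0.844 over 9 alternatives. For shared clonotypes limma called 0 of 5242, with 277 at an unadjusted p under 0.05. Expanded clonotypes held 0.293% ± 0.200 in MMTV-PyMT mice and 0.0857% ± 0.118 in WTNT mice (permutation p 0.0391, adjusted 0.139), and the 10 most abundant held 0.845% ± 0.175 against 0.675% ± 0.112 (permutation p 0.0529, adjusted 0.169). Both differences had the other sign in raw reads, at -0.0105 and -0.0117 percentage points. Overlap did not differ (permutation p 0.396).

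At d95, 2 public receptors present in every R mouse had no read in any NR mouse. TRBV5 TRBJ2-7 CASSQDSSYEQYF was found in 5 of 5 R mice at 388 ± 263 normalised CPM, 12.1-fold the NR floor of 3 reads per library, and in 0 of 3 NR mice. Its limma log2 difference was 5.12 ± 0.85 (SE, adjusted p 0.00365). TRBV26 TRBJ2-7 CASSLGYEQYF was found in 5 of 5 R mice at 326 ± 223, also 12.1-fold the NR floor, and in 0 of 3 NR mice (limma log2 4.83 ± 0.86, adjusted p 0.0053). Where the first was read, it had 35 to 233 reads at d95, and NR replicate 1 had only 90648 reads and 2470 clonotypes in all. The median reads per clonotype in the d95 NR libraries were 25 to 31. The floor covers the counting of reads and not the sampling of molecules, so both folds are no lower bounds. The count of calls was 2 without each library in turn, 0 with a pseudocount of 1 CPM and 0 among clonotypes found in 80% of libraries. That last filter removes both before testing, since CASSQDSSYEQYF was found in 11 and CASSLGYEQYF in 8 of 14 d95 libraries. Limma called these 2 of 964 shared clonotypes, with 79 at an unadjusted p under 0.05. Neither was particular to R mice at d95. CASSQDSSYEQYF was also in 3 of 3 PLX+PTX mice at 577 ± 99.2 and in 3 of 3 PTX mice at 320.5 ± 52.8. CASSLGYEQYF was also in 3 of 3 PLX+PTX mice, and in 0 of 3 PTX mice. At d105, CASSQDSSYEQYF was in 6 of 6 R mice at 252 ± 83.2 and in 4 of 4 NR mice at 241 ± 41.7. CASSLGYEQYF was then in 3 of 6 R mice at 138 ± 197 and in 4 of 4 NR mice at 115 ± 5.64, so that its detection ran the other way.

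**Figure D1:**
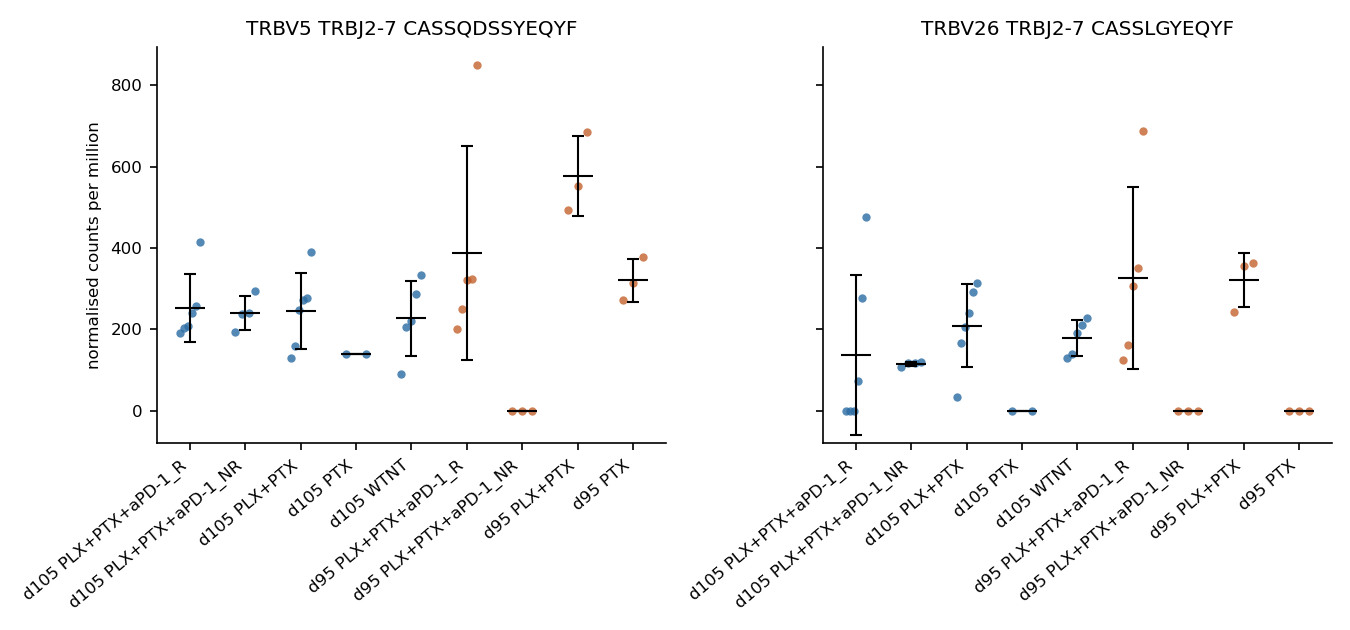
Normalised counts CPM of TRBV5 TRBJ2-7 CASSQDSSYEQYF and TRBV26 TRBJ2-7 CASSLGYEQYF in each of the 37 libraries by group, with points for libraries, bars for group means and whiskers for SD. At d95 both are at 0 in the 3 NR libraries and above 0 in the 5 R libraries.

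Segments gave less at d95. TRBV19 held 4.83% ± 0.64 in R (n = 5) and 6.14% ± 1.02 in NR (n = 3), a log2 difference of -0.34 ± 0.12 (SE, limma adjusted p 0.381). Its share was 7.31% in NR replicate 1, against 5.71% and 5.41% in the other NR libraries. Adjusted over the list alone, TRBV19 passed in the superantigen list (1 segment, adjusted p 0.0477) and in the invariant T cell list (1 segment), against 0 over all tested, and 0 passed in the TRBJ1 and TRBJ2 lists. Limma called 0 of 24 segments with 1 at an unadjusted p under 0.05, edgeR 0 with 1 and DESeq2 0 with 0. TRBV1 (-0.14), TRBV26 (0.11) and TRBV29 (-0.06) differed by less. The 10 most abundant clonotypes held 1.02% ± 0.151 in R and 2.47% ± 1.57 in NR, and expanded clonotypes 0.512% ± 0.246 against 7.30% ± 10.1, each at the smallest p that 56 regroupings can give (exact permutation p 0.0179, adjusted 0.0952). NR replicate 1, the library with 90648 reads, held 4.27% and 19.0%, and without it the NR means were 1.57% ± 0.209 and 1.47% ± 0.213 (n = 2), with differences R minus NR of -0.544 and -0.958 percentage points. Overlap within R and NR was 0.149 and 0.0670, against 0.0972 between them (exact permutation p 0.0357, adjusted 0.233).

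Adding aPD-1 to PLX+PTX at d95 was examined in 8 against 3 mice. TRBV20 held 1.47% ± 0.78 with aPD-1 and 0.619% ± 0.82 without (log2 2.23 ± 0.90), and TRBV3 13.6% ± 1.59 against 8.86% ± 4.04 (log2 0.72 ± 0.23). Both were chosen after their values were seen and had a limma adjusted p of 0.199. TRBV1 (-0.42), TRBV19 (0.09), TRBV26 (0.16) and TRBV29 (0.20) did not pass either. Limma called 0 of 24 segments with 4 at an unadjusted p under 0.05, edgeR 0 with 8 and DESeq2 0 with 7, and adjusted over the list alone 0 segments of every tested list passed, as over all tested. Without PLX+PTX replicate 1, 12 segments passed, led by TRBV20 at 3.50 and TRBV3 at 1.05 (adjusted p 0.00487), whose adjusted p over 9 alternatives that kept all libraries ran from 0.0725 to 0.396. Among 964 shared clonotypes limma called 0, with 64 at an unadjusted p under 0.05. Richness was 19718 against 15643 (exact permutation p 0.225), and overlap did not differ (exact permutation p 0.945).

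Adding PLX3397 to PTX at d95 was examined in 3 against 3 mice, where 0.1 is the smallest p an exact permutation test can give. The PTX floor of 3 reads per library covers the counting of reads only and gives no lower bound. TRBV26 TRBJ2-7 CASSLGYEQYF was found in 3 of 3 PLX+PTX mice at 321 ± 66.6 normalised CPM, 23.2-fold that floor, and in 0 of 3 PTX mice (limma log2 5.02 ± 0.96, adjusted p 0.0271). It was the 1 call among 964 shared clonotypes, with 59 at an unadjusted p under 0.05, and 0 were called without any 1 of the 6 libraries in turn. TRBV1 (0.04), TRBV19 (-0.29), TRBV26 (-0.21) and TRBV29 (-0.09) did not pass. Limma called 0 of 24 segments with 0 at an unadjusted p under 0.05, edgeR 0 with 1 and DESeq2 0 with 0, and adjusted over the list alone 0 segments of every tested list passed, as over all tested. Without PLX+PTX replicate 1, TRBV26 passed at -0.36 (adjusted p 0.0476), against 0.952 to 0.996 over 9 alternatives that kept all libraries. Richness was 15643 ± 5375 against 15395 ± 1878 (exact permutation p 1).

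The days d105 and d95 were compared over the 4 MMTV-PyMT treatments, each group against its own at the other day. TRBJ2-5 rose from 11.5% ± 0.956 at d95 (n = 14) to 20.1% ± 1.36 at d105 (n = 18), a log2 difference of 0.81 ± 0.04 (limma adjusted p 4.37e-17), and lay above the d95 mean of its own treatment in 18 of 18 d105 mice. TRBJ1-6 fell from 5.06% ± 0.379 to 2.56% ± 0.193 (log2 -0.99 ± 0.04, adjusted p 2.87e-19, in 18 of 18). Among variable segments, TRBV24 fell from 14.4% ± 3.76 to 7.68% ± 0.825 (log2 -0.87 ± 0.08, adjusted p 2.92e-10, in 18 of 18), TRBV1 from 10.9% ± 3.06 to 7.02% ± 0.498 (log2 -0.60 ± 0.08, adjusted p 2.11e-07, in 18 of 18) and TRBV19 from 5.38% ± 0.843 to 3.81% ± 0.698 (log2 -0.49 ± 0.08, adjusted p 2.51e-06, in 18 of 18). TRBV26 rose from 8.05% ± 0.810 to 11.7% ± 1.29 (log2 0.54 ± 0.05, adjusted p 2.66e-10, in 18 of 18), and TRBV20 from 1.04% ± 0.846 to 1.96% ± 0.590 (log2 1.51 ± 0.37, adjusted p 0.000473, in 16 of 18). In raw reads most of these differences were smaller, at 0.30 for TRBJ2-5, -0.56 for TRBJ1-6, -0.31 for TRBV24, -0.36 for TRBV1, -0.18 for TRBV19 and 0.34 for TRBV26, and that of TRBV20 was larger, at 1.92.

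Limma called 20 of 24 segments between days, 10 higher and 10 lower at d105, while edgeR called 17 and DESeq2 16. The others higher were TRBJ1-5 (0.69), TRBJ2-4 (0.69), TRBJ2-3 (0.64), TRBV3 (0.54), TRBV5 (0.30), TRBV23 (0.29) and TRBJ2-1 (0.21), and the others lower were TRBJ2-7 (-0.46), TRBJ1-2 (-0.41), TRBJ2-2 (-0.38), TRBJ1-1 (-0.21), TRBJ1-3 (-0.20) and TRBV2 (-0.14). In raw reads TRBV2, TRBJ1-1, TRBJ1-2, TRBJ1-3 and TRBJ2-1 took the other sign, as did TRBJ2-3 in edgeR and DESeq2 and TRBV5 in DESeq2. Some passed the threshold in that opposite direction. TRBJ1-1 did so in raw reads (0.26, limma adjusted p 1.64e-05), edgeR (0.16, 0.000293) and DESeq2 (0.14, 0.000121), TRBJ2-1 in edgeR (-0.18, 0.00121) and DESeq2 (-0.21, 0.00186), and TRBV2 in raw reads (0.13, 0.0494). TRBV5, TRBJ1-2, TRBJ1-3, TRBJ2-1, TRBJ2-2 and TRBJ2-3 lost their calls in raw reads, where TRBV29 (0.63), TRBV30 (0.52) and TRBV4 (0.36) passed. TRBJ2-4 lost its call in edgeR (0.05) and DESeq2 (0.02), as did TRBV2, TRBV5, TRBJ1-2, TRBJ1-3 and TRBJ2-3 in both and TRBV3 in DESeq2. In nb clone counts TRBV2, TRBJ1-1 and TRBJ1-3 lost theirs, as did TRBJ1-5 and TRBJ2-1 with each clonotype counted once. TRBV29 (0.08), TRBV30 (-0.09) and TRBV4 (0.08) did not pass in normalised counts, but all 3 passed in edgeR (0.53, 0.43 and 0.26) and DESeq2 (0.51, 0.41 and 0.24). TRBV29 (0.32) and TRBV4 (0.20) also passed in nb clone counts, and TRBV4 (0.16) and TRBJ1-4 (-0.09) with each clonotype counted once. TRBJ1-5 lost its call without d105 PTX replicate 2 (0.62, adjusted p 0.0631), d95 PLX+PTX replicate 2 (0.57, 0.0823) or replicate 3 (0.64, 0.0507), or d95 PTX replicate 3 (0.62, 0.0529), and TRBV29 passed without d95 PLX+PTX replicate 3 (0.11, adjusted p 0.0474), as did TRBV4 without it (0.10, 0.0474) or replicate 1 (0.10, 0.0422). Adjusted over the list alone and over all tested alike, 2 superantigen segments, 2 invariant T cell segments, 5 TRBJ1 segments and 6 TRBJ2 segments passed. The TRBJ1 cluster held 15.0% ± 0.73 of normalised counts at d105 and 19.4% ± 1.24 at d95, but 24.2% ± 0.75 and 24.7% ± 1.76 of reads.

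**Figure D2:**
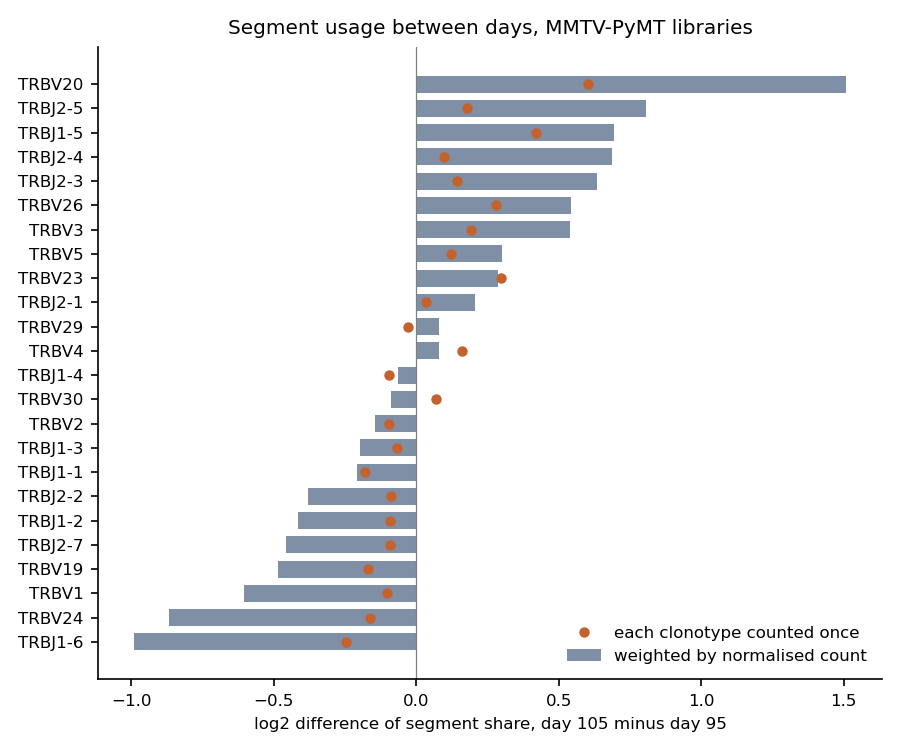
Log2 difference, d105 minus d95, of the 24 tested segments in MMTV-PyMT mice, with bars for shares weighted by normalised count and dots for shares with each clonotype counted once. The slope of dots on bars is 0.317.

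Richness at 222369 reads was 42583 ± 10590 at d105 (n = 18) and 17780 ± 4429 at d95 (n = 13). Clonality was 0.0579 ± 0.0043 against 0.0512 ± 0.0022. Both had a permutation p of 1e-05, the smallest they can give (adjusted 0.00016). Thinning makes reads equal but not the number of molecules sampled, so the richness difference may still reflect yield. The 10 most abundant clonotypes held 0.845% ± 0.175 against 1.41% ± 0.873 (permutation p 4e-05, adjusted 0.000427), and expanded clonotypes 0.293% ± 0.200 against 2.10% ± 4.88 (permutation p 7e-05, adjusted 0.00056). Without d95 NR replicate 1, the differences of these shares were -0.385 (adjusted 0.00117) in place of -0.593 and -0.588 (adjusted 0.00144) in place of -1.88 percentage points. Neither passed in raw reads, at -0.0814 (adjusted 0.993) and -1.51 (adjusted 0.993), or in nb clone counts, at -0.275 (adjusted 0.229) and -1.91 (adjusted 0.381), where adjusted p values of the other alternatives were at most 0.00904. Clonality took the other sign without passing in raw reads, at -0.00137, and in nb clone counts, at -0.000305, and it did not pass without clonotypes of 1 read (adjusted 0.108). The mean CDR3 length was 13.8 amino acids at d105 and 13.7 at d95 (permutation p 1e-05, adjusted 8e-05), and raw reads gave the opposite difference, -0.0478, also past the threshold (permutation p 2e-05, adjusted 0.00016). In nb clone counts the difference was -0.00168 (permutation p 0.844).

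**Figure D3:**
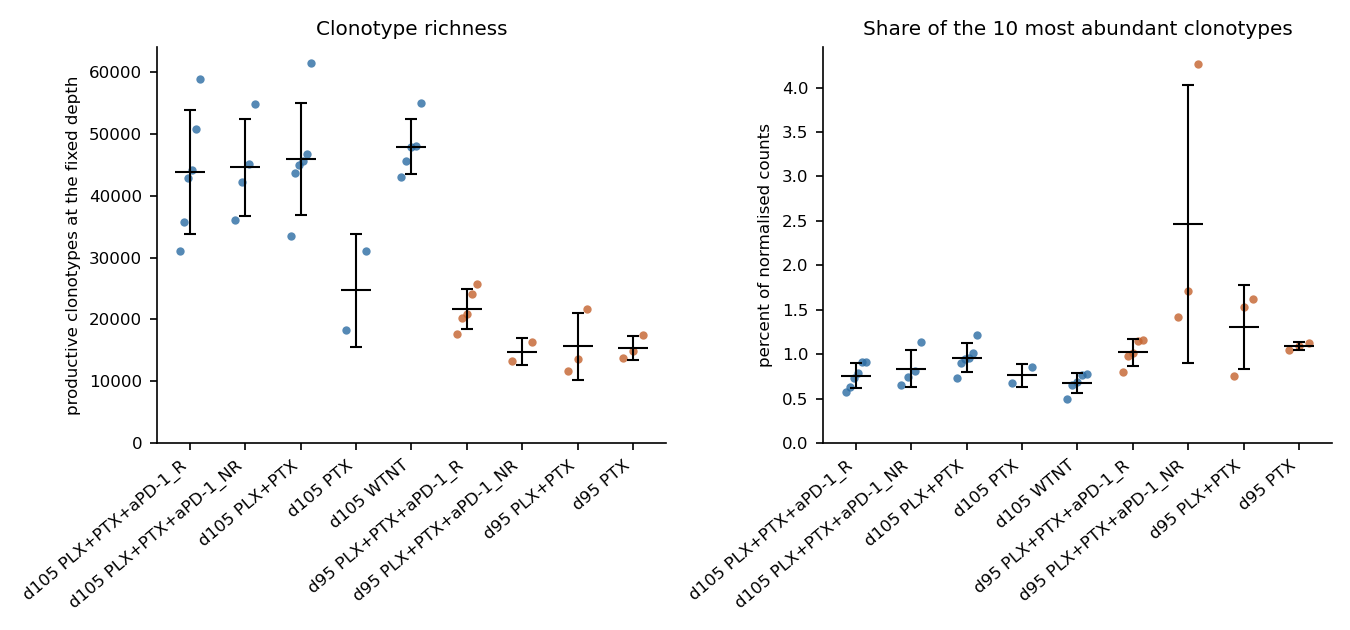
Richness at 222369 reads (clonotypes) and share of the 10 most abundant clonotypes (percent of normalised counts) per library in 9 groups, with points for libraries, bars for means and whiskers for SD. Libraries of d105 are in blue and those of d95 in orange, and mean richness in MMTV-PyMT mice was 42583 and 17780.

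Of 2394 shared clonotypes, limma called 141 between days, 128 higher and 13 lower at d105, with 454 at an unadjusted p under 0.05. In libraries thinned to equal depth it called 42 of 1876, 27 higher and 15 lower, 37 of them among the 141. With detection in 80% of libraries it called 3 of 209, and with a pseudocount of 1 CPM 239, 236 higher and 3 lower. The lowest p values among those higher belonged to TRBV4 TRBJ2-5 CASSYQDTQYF (log2 3.20 ± 0.41, adjusted p 2.47e-05, found in 16 of 18 mice at d105 and 1 of 14 at d95) and TRBV5 TRBJ2-5 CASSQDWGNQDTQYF (3.92 ± 0.53, adjusted p 3.05e-05, 17 of 18 and 2 of 14). They were followed by TRBV3 TRBJ2-5 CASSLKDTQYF (2.28), TRBV13-2 TRBJ2-5 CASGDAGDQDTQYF (3.47), whose segment is on the deletion list, and TRBV2 TRBJ2-7 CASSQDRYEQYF (2.52). No d95 PLX+PTX or PTX library had a read of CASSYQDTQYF, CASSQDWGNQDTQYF or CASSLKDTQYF, so their log2 differences are fitted values and no bounds. The authors' factors of their segment pairs are high, at 15.2, 63.1 and 13.25, and d95 libraries had fewer reads, so absence there may reflect depth. In raw reads their differences were 1.37, 0.87 and 0.92. In thinned libraries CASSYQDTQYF (3.10) and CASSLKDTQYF (2.10) were still called. Those lower were led by TRBV26 TRBJ2-7 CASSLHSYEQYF (-3.06 ± 0.44, adjusted p 7.04e-05, found in 5 of 18 and 13 of 14) and TRBV3 TRBJ1-6 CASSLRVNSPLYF (-2.91 ± 0.42, adjusted p 7.04e-05, 4 of 18 and 12 of 14). They were followed by TRBV19 TRBJ2-7 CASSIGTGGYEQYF (-1.48), TRBV19 TRBJ2-7 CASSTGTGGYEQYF (-1.92) and TRBV1 TRBJ1-2 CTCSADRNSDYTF (-1.36). Of these 10, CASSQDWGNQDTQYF was not tested in thinned libraries, only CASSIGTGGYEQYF was tested with detection in 80%, and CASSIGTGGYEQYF and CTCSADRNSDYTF were not called in raw reads or with a pseudocount of 1 CPM.

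Whether treatment effects changed between days was tested directly. For R minus NR, limma called 0 of 24 segments with 0 at an unadjusted p under 0.05, and 2 of 2394 shared clonotypes, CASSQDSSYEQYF (change -5.09 ± 0.62, adjusted p 7.52e-06) and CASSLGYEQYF (-6.21 ± 1.25, adjusted p 0.0303). Without d95 NR replicate 1, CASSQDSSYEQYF alone was called. The change of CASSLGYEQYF, which is at 0 in every d95 NR mouse, was then the same with a wider SE of 1.38 (adjusted p 0.0853, from 0.0246 to 0.0853 over 3 alternatives), and it was not called in raw reads either (-5.45 ± 1.23). TRBV1 TRBJ2-1 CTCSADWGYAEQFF was called in raw reads (-6.06) and nb clone counts (-4.20) but not in normalised counts. For aPD-1 added to PLX+PTX, TRBV3 was the 1 segment called (-0.70 ± 0.20, adjusted p 0.0437) and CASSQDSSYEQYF the 1 shared clonotype (2.72 ± 0.54, adjusted p 0.0493). Without d95 NR replicate 1, limma called 0 of either, with TRBV3 at -0.69 ± 0.21 and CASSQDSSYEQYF at 2.26 ± 0.55. TRBV3 was not called with each clonotype counted once (-0.16 ± 0.08), nor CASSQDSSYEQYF in raw reads (2.18 ± 0.48) or nb clone counts (2.41 ± 0.58). TRBJ1-1 was called in raw reads (-0.42) and nb clone counts (-0.32), and TRBV24 (0.35) and TRBJ2-3 (0.26) in raw reads. For PLX3397 added to PTX, 0 segments were called by limma with 1 at an unadjusted p under 0.05, and 2 shared clonotypes were, TRBV1 TRBJ2-3 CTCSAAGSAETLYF (5.25 ± 1.05, adjusted p 0.0261) and TRBV24 TRBJ2-7 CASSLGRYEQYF (-5.09 ± 0.96, adjusted p 0.0214). In raw reads the former was not called, at a larger change of 7.31 ± 1.54, and TRBJ1-6 was (0.30). No change between days of a scalar measure passed (lowest adjusted permutation p 0.502). Permuting days within treatments assumes no day effect, so the large differences between days widen the permuted values and can hide a change. For PLX3397 added to PTX, the change in richness was 20988 (permutation p 0.127, adjusted 0.637). These tests therefore do not show that the effects stayed the same.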

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

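The tests of carry-over, of an intact TRBV locus, of yield for joining and variable segments apart, of read weights and the authors' factors apart, of library yield against the TRBV1 and TRBV24 ratio and all counts over other splits were chosen only after the result was seen, as were the contrasts between days for shared clonotypes. In 5 of 150 groups of values, 1 library lay far from the others, where chance gives about 1 in 20. At d105, clonality in PLX+PTX replicate 2 was 0.0674 (others 0.0554 to 0.0594). TRBV24 held 6.11% in NR replicate 1 (others 8.28% to 8.52%) and TRBV26 held 14.4% in it (others 10.2% to 10.4%). TRBV24 held 8.54% in PLX+PTX replicate 1 (others 6.94% to 7.24%), and TRBJ2-2 held 5.22% in it (others 5.51% to 5.68%).

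In 6 cases an effect differed between days by limma. For R minus NR the change was -6.21 for TRBV26 TRBJ2-7 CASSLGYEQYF and -5.09 for TRBV5 TRBJ2-7 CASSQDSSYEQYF. For aPD-1 added to PLX+PTX it was -0.70 for TRBV3 and 2.72 for TRBV5 TRBJ2-7 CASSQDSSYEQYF. For PLX3397 added to PTX it was 5.25 for TRBV1 TRBJ2-3 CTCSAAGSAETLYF and -5.09 for TRBV24 TRBJ2-7 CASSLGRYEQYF. For the clonotypes these fitted values rest on some groups in which every library was at 0 and are no bounds. The 2 calls of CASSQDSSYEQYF are not separate findings, since the aPD-1 side pools R and NR and both draw on its absence from the 3 d95 NR libraries. Without d95 NR replicate 1, the library with 90648 reads, 3 of these calls end. For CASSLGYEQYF the change stays at -6.21, since all 3 d95 NR mice are at 0, with an SE of 1.38 in place of 1.25, and for aPD-1 the change becomes -0.69 for TRBV3 and 2.26 for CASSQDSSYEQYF, with SEs of 0.21 and 0.55 in place of 0.20 and 0.54.

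Segment shares differed widely between d105 and d95, with TRBJ2-5 and TRBV26 higher and TRBJ1-6 and TRBV24 lower at d105. The 20 segments and 141 shared clonotypes of the real split were reached in 1 of 100 splits each, the real one (highest others 6 and 5). That is the smallest share 100 splits can give, in tests chosen after the result was seen. The share alone therefore does not exclude chance, though the real counts lay far above those of every other split. With each clonotype counted once the differences shrank, with a slope of 0.317 (95% bootstrap interval 0.258 to 0.367) over 24 segments, but this drops both the weight by reads and the authors' factors. Taken apart, the slope was 0.702 (0.643 to 0.770) with these factors as the only weights, 0.353 (0.288 to 0.410) for clonotypes counted once on raw reads and 0.640 (0.516 to 0.746) for raw reads on normalised counts, so over all segments primer or PCR efficiency that differed between both sets of libraries and the authors' factors cannot be told apart. In the same order the slopes were 0.815 (0.686 to 0.911), 0.480 (0.339 to 0.602) and 0.361 (0.3 to 0.459) for joining segments, where the last is in line with differences enlarged by the factors, and 0.613 (0.544 to 0.759), 0.325 (0.248 to 0.381) and 0.853 (0.750 to 0.896) for variable segments, where the factors stay open. Reads per library as a covariate left 0.622 of the median difference (0.515 to 1.01), 0.894 (0.720 to 1.28) for the 11 called joining segments, such as TRBJ2-5 at 0.89 and TRBJ1-6 at -0.89, and 0.463 (0.341 to 1.01) for the 9 called variable segments, such as TRBV1 at -0.16 and TRBV20 at 0.36, so lower yield at d95 cannot be told apart from the day, as these intervals are wide and the ranges of reads do not overlap, and a run or batch and age remain open and untested.

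TRBV13-2 TRBJ2-5 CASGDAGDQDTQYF and other clonotypes of the FVB/N deletion list were read in most d105 libraries. Its read share and that of TRBV13-1 TRBJ1-2 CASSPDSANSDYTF rose and fell together over 23 libraries, 1 of 4 relations computed. Spearman's rho was 0.720 (permutation p 0.00017, adjusted 0.00034) and Pearson's r 0.693 (permutation p 9e-05). Without PLX+PTX replicate 5 and WTNT replicate 4 the relation was weaker, with rho 0.646 and r 0.586. This is consistent with carry-over of a few foreign clonotypes, the top 3 of which held 82.5% of the list's 72046 reads. The tables argue against mice with an intact TRBV locus in 36 libraries, where the list held at most 0.249% of clonotypes (95% Wilson interval 0.193 to 0.321; median of all 37 libraries 0.0736%), and leave it open in d95 NR replicate 1 alone, at 0.567% (14 of 2470, 0.338 to 0.949). No other biological explanation was tested.

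Some d95 libraries had high TRBV1 and TRBV24 with low TRBV3 and TRBV20. The log2 ratio of these pairs fell with reads over 14 libraries (Spearman's rho -0.684, permutation p 0.0091, adjusted 0.0146; Pearson's r -0.431, permutation p 0.126; r -0.722 without NR replicate 1 and PLX+PTX replicate 3), while rho was -0.0514 over the 23 d105 libraries. The SD of the ratio with each clonotype counted once was 0.241 of the weighted SD (95% bootstrap interval 0.192 to 0.348) and 0.251 (0.195 to 0.366) of that in raw reads, but 0.482 (0.386 to 0.637) of the weighted SD with the authors' factors as the only weights, so PCR efficiency alone stays open. The SD in raw reads was 0.959 (0.908 to 0.992) of the weighted one, which argues against the authors' factors as the cause. Low yield may contribute, and a treatment effect was not told apart from it. For aPD-1 added to PLX+PTX at d95 limma gave -0.42 for TRBV1, -0.43 for TRBV24, 0.72 for TRBV3 and 2.23 for TRBV20 (adjusted p 0.199 each). These segments define the ratio, so the values are no separate support. Without PLX+PTX replicate 1 (780923 reads, log2 ratio 0.467), 12 segments passed. That leaves replicates 2 and 3, with 346851 and 222369 reads and log2 ratios of 3.05 and 1.76. These calls therefore cannot separate treatment from yield.

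The counts of the treatment comparisons were set against other splits of the same mice. Where the real count was 0, every split reaches it by definition, 100 of 100 splits or 56 of 56, which says nothing on chance. For segments with a real count of 0, the highest other split called 10 for R against NR at d105, 4 for aPD-1 added to PLX+PTX at d105, 11 for MMTV-PyMT against WTNT, 12 for aPD-1 added to PLX+PTX at d95 and 0 for R against NR at d95. The median of the other splits was 0 in each, so single splits with 10 to 12 segments may reflect a structure of the samples or chance, which were not tested apart. For shared clonotypes with a real count of 0 the highest other splits called 2, 3, 3 and 2 in the first 4 of these comparisons. For R against NR at d95 the real count was 2 shared clonotypes, reached in 1 of 56 splits, the real one (highest other 1), which is the smallest share they can give. Taken alone this share lies under 0.05, but it is 1 of 14 such tests, all chosen after the result was seen, so chance is not excluded. The share also says nothing on the 0 calls with a pseudocount of 1 CPM or with detection in 80% of libraries, a filter that removes both clonotypes before testing. PLX+PTX against PTX at d95 allows 10 splits, too few for a share under 0.05, with real counts of 0 segments (highest other 6) and 1 shared clonotype (highest other 0).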

How the results depend on the processing

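Alternatives chosen only after the data were seen are the nb clone counts, repeats without the FVB/N deletion segments, and raw counts or other settings for shared clonotypes, overlap and changes between days. Of 2507 alternative values, 703 from other settings and 1630 from leaving out 1 library kept their direction and side of the threshold or, for counts of calls, stayed within 1.5 times of the main count. A count of 0 that stayed at 0 is among these. Of the rest, 66 and 32 reversed, 18 and 4 lost a call, 9 and 7 gained one, and 27 and 11 counts moved by over 1.5 times. No paired analysis was possible because replicate numbers follow the order of deposition only. The alternative with all listed clonotypes was not run, since 0 unproductive entries were listed. Short names stand for the comparisons, as d105 aPD-1 for aPD-1 added to PLX+PTX at d105 and d105 PLX3397 for PLX3397 added to PTX. Segment values are log2 differences and shares are differences in percentage points. Detection in 80% of libraries removes both d95 clonotypes by construction, and for the other values the cause was not tested.

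With raw clone counts, d105 aPD-1 gave expanded share 0.0546 and TRBV1 -0.0066, and d105 PLX3397 gave clonality -0.00342, top 10 share -0.159, expanded share -0.235, segments called 2 and TRBV29 0.0275. MMTV-PyMT/WTNT gave top 10 share -0.0117 and expanded share -0.0105, and d95 aPD-1 gave clonality -0.00347. d95 PLX3397 gave mean CDR3 length 0.0292, and d105 minus d95 gave clonality -0.00137, top 10 share -0.0814, expanded share -1.51, mean CDR3 length -0.0478, TRBV2 0.13, TRBJ1-1 0.26, TRBJ1-2 0.0484, TRBJ1-3 0.12 and TRBJ2-1 -0.0791. d105 R/NR gave TRBV26 -0.0047, and d95 R/NR gave TRBV29 0.0385.

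With merged amino acid clonotypes, d95 R/NR gave clonality 0.00121.

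With clonotypes of 1 read left out, MMTV-PyMT/WTNT gave mean CDR3 length 0.000898, and d105 minus d95 gave clonality 0.00200.

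With thinned libraries, MMTV-PyMT/WTNT gave clonality -0.000301, and d95 aPD-1 gave clonality -0.0011, top 10 share -0.138 and expanded share -0.291. d105 minus d95 gave shared clonotypes called 42.

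With d95 NR replicate 1, the low library, left out, d95 R/NR gave clonality 7.61e-05, and d95 aPD-1 gave top 10 share -0.128 and expanded share -0.264.

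With nb clone counts (chosen after seeing the data), d105 R/NR gave top 10 share 0.00813, and d105 PLX3397 gave clonality -0.000132, top 10 share -0.0375 and segments called 2. d95 aPD-1 gave clonality -0.000348, and d95 PLX3397 gave mean CDR3 length 0.0111. d105 minus d95 gave clonality -0.000305, top 10 share -0.275, expanded share -1.91, mean CDR3 length -0.00168 and TRBJ1-1 0.0032, and change of PLX+PTX+aPD-1 minus PLX+PTX gave segments called 2 and shared clonotypes called 0.

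With the Jaccard index of thinned libraries, d105 R/NR gave clonotype overlap 9.9e-05, and d105 aPD-1 gave clonotype overlap -0.00038. d95 aPD-1 gave clonotype overlap 0.00194, and d95 PLX3397 gave clonotype overlap 0.000365.

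With each clonotype counted once, d105 R/NR gave segments called 1, and MMTV-PyMT/WTNT gave segments called 2. d105 aPD-1 gave TRBV1 -0.02, and d105 PLX3397 gave TRBV29 0.12. d95 R/NR gave TRBV29 0.078, and d95 aPD-1 gave TRBV19 -0.0252 and TRBV29 -0.0663. d95 PLX3397 gave TRBV1 -0.0252 and TRBV29 0.0307, and d105 minus d95 gave TRBV29 -0.0299.

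With raw clone counts (chosen after seeing the data), d105 aPD-1 gave shared clonotypes called 1, and change of PLX+PTX+aPD-1 minus PLX+PTX gave segments called 4 and shared clonotypes called 0. Change of PLX+PTX minus PTX gave segments called 1 and shared clonotypes called 1.

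With no filter on the share, d105 PLX3397 gave segments called 1, which was TRBV12-2 at -0.39.

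With edgeR on reads, d105 PLX3397 gave segments called 2 and TRBV29 0.011, and d105 R/NR gave TRBV26 -0.0294. d95 R/NR gave TRBV29 0.038, and d105 minus d95 gave TRBV2 0.0281, TRBJ1-1 0.16, TRBJ1-3 0.0199, TRBJ2-1 -0.18 and TRBJ2-3 -0.0454.

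With DESeq2 on reads, d105 PLX3397 gave segments called 2 and TRBV29 0.013, and d105 R/NR gave TRBV26 -0.0329. d95 R/NR gave TRBV29 0.0407, and d105 minus d95 gave TRBV2 0.012, TRBV5 -0.0178, TRBJ1-1 0.14, TRBJ1-3 0.0018, TRBJ2-1 -0.21 and TRBJ2-3 -0.0696.

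With pseudocount 50 CPM, d105 PLX3397 gave shared clonotypes called 3.

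With detection in 80% of libraries, d105 PLX3397 gave shared clonotypes called 2, and d95 R/NR gave shared clonotypes called 0. d95 PLX3397 gave shared clonotypes called 0, and d105 minus d95 gave shared clonotypes called 3.

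With pseudocount 1 CPM, d95 R/NR gave shared clonotypes called 0, and d95 PLX3397 gave shared clonotypes called 0. d105 minus d95 gave shared clonotypes called 239.

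With d95 NR replicate 1, the low library, left out, (chosen after seeing the data), change of aPD-1 R minus NR gave shared clonotypes called 1, and change of PLX+PTX+aPD-1 minus PLX+PTX gave segments called 0 and shared clonotypes called 0.

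With each clonotype counted once (chosen after seeing the data), change of PLX+PTX+aPD-1 minus PLX+PTX gave segments called 0.

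With the mouse number block as covariate, d105 aPD-1 gave TRBV29 0.0042.

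Leaving out 1 library at a time gave the following ranges. Richness for d105 R/NR ran from -3657 (without d105 R replicate 2) to 2768 (without d105 NR replicate 3). Top 10 share for d105 R/NR ran from -0.139 (without d105 NR replicate 3) to 0.0224 (without d105 NR replicate 1). Expanded share for d105 R/NR ran from -0.141 (without d105 NR replicate 3) to 0.0272 (without d105 NR replicate 1). Richness for d105 aPD-1 ran from -4281 (without d105 PLX+PTX replicate 2) to 1326 (without d105 PLX+PTX replicate 4). Clonality for d105 PLX3397 ran from -0.00155 (without d105 PLX+PTX replicate 2) to 0.000859 (without d105 PLX+PTX replicate 6). Clonality for d95 R/NR ran from -0.00101 (without d95 R replicate 1) to 0.000366 (without d95 R replicate 3). Top 10 share for d95 aPD-1 ran from -0.128 (without d95 NR replicate 1) to 0.417 (without d95 PLX+PTX replicate 2). Expanded share for d95 aPD-1 ran from -0.264 (without d95 NR replicate 1) to 2.43 (without d95 R replicate 1). Clonality for d95 PLX3397 ran from -1.42e-05 (without d95 PTX replicate 3) to 0.00191 (without d95 PTX replicate 1). Richness for d95 PLX3397 ran from -2803 (without d95 PLX+PTX replicate 1) to 2265 (without d95 PLX+PTX replicate 2). Segments called for d105 R/NR ran from 0 (without d105 R replicate 1) to 7 (without d105 NR replicate 1). Shared clonotypes called for d105 PLX3397 ran from 0 (without d105 PLX+PTX replicate 1) to 2 (without d105 PTX replicate 1). Segments called for d95 aPD-1 ran from 0 (without d95 R replicate 1) to 12 (without d95 PLX+PTX replicate 1). Segments called for d95 PLX3397 ran from 0 (without d95 PLX+PTX replicate 2) to 1 (without d95 PLX+PTX replicate 1). Shared clonotypes called for d95 PLX3397 came to 0 without any 1 library in turn. TRBV1 for d105 R/NR ran from -0.0311 (without d105 NR replicate 1) to 0.067 (without d105 NR replicate 4). TRBV1 for d105 PLX3397 ran from -0.10 (without d105 PTX replicate 1) to 0.14 (without d105 PTX replicate 2). TRBV29 for d105 PLX3397 ran from -0.10 (without d105 PTX replicate 1) to 0.0217 (without d105 PTX replicate 2). TRBV26 for MMTV-PyMT/WTNT ran from -0.0082 (without d105 WTNT replicate 3) to 0.0345 (without d105 PTX replicate 2). TRBV1 for d95 R/NR ran from -0.28 (without d95 NR replicate 3) to 0.0084 (without d95 NR replicate 1). TRBV29 for d95 aPD-1 ran from -0.0123 (without d95 PLX+PTX replicate 2) to 0.32 (without d95 PLX+PTX replicate 3). TRBV1 for d95 PLX3397 ran from -0.27 (without d95 PLX+PTX replicate 2) to 0.33 (without d95 PLX+PTX replicate 1). TRBV29 for d95 PLX3397 ran from -0.20 (without d95 PLX+PTX replicate 3) to 0.13 (without d95 PLX+PTX replicate 2).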

Other observations

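The TRBV19 comparison was chosen only after the result was seen. TRBV19 was lower in R than in NR mice by the same log2 difference of -0.34 at both days, past the threshold over all segments at neither. At d95, NR replicate 1, the library with 90648 reads, held 7.31%, against 5.71% and 5.41% in the other NR libraries. The size of the d95 difference, and so its match with d105, rests in part on that library. The change of this difference between days was 0.01 ± 0.21 (SE, limma adjusted p 0.982). Over 10 alternatives at d105 and 9 at d95 that kept all libraries, the difference ran from -0.34 to -0.26 at d105 and from -0.34 to -0.11 at d95.

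The libraries with the highest overlap of reads were d105 R replicate 3 and WTNT replicate 4, with a Morisita-Horn index of 0.478, against a median of 0.130 over all pairs. Without the segments of the FVB/N deletion list this pair had an index of 0.160.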
